A study of Mus musculus with 6 samples.

How the data were processed

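Gene expression was measured in 6 mouse teratomas, 3 injected with a microRNA negative control and 3 with a mimic of miR-124a-3p. A teratoma is a tumour of mixed tissues that embryonic stem cells form when placed under the skin of an animal that cannot reject them, here BALB/c nude mice. Per the labels, mice were randomised to 2 groups of 3, so each array stands for a tumour of a different mouse, and RNA came from 1 of 2 pieces of each tumour. Per the labels' protocols, total RNA was purified with a column kit, labelled with Cy3 and hybridised to 1-colour Agilent arrays. The arrays report messenger RNA and long noncoding RNA, and the level of the mimic itself was not analysed here.

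The deposited scanner files give a spot intensity that, per the file headers, Agilent Feature Extraction 11.5.1.1 had corrected for background and for trends across the array, with low values replaced by surrogates. They are not scaled between arrays. The deposited value table holds log2 values by the authors. Against the scanner files its columns were the log2 processed intensity shifted by a constant per array, with an SD of the difference of 0.0029 and a 75th percentile of 0.01 in every column. It was not centred per probe, its direction is that of signal, and its medians were -2.98, -3.07 and -2.98 for control 1 to 3 and -2.97, -2.99 and -2.98 for miR-124a 1 to 3. The tool that made this table is not given in the sources used here.

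Each array holds 62976 spots, of which 59305 are not control spots. Spots of 1 probe were averaged, which gave 56605 probes, and 22 probes flagged as outliers were left out. Between 35887 and 37304 probes per array (63.4% to 65.9%) were well above background, and 0 spots were saturated on any array. The number of arrays limits the precision. Values are log2 of the processed intensity minus the array's 75th percentile. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which left 35719 probes. A gene was represented by its brightest tested probe, and 8228 genes had more than 1 tested probe. Gene names were taken from the accession where the GRCm38.p6 RefSeq table held it (32994 probes), or else from the symbol (10224) or an older symbol (520); 12867 probes kept the name in the file. Probe positions are those of the array annotation, build mm9. For a gene not well above background on any array of a group, the fold is a bound: the brighter group's mean against the dimmer group's mean of, per array, the higher of its own signal and the lowest signal among probes well above background. Such a bound, written as at least, allows for the floor of the signal and not for the spread between tumours, so it is not a confidence limit.

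Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 6 arrays without covariates, with Benjamini-Hochberg adjustment over 22946 genes and a threshold of 0.05. Gene lists with at least 5 tested members were compared with fry, two-sided, with Benjamini-Hochberg adjustment over 35 lists. The fry p asks whether the genes of a list move, on balance, 1 way, and does not compare the list with other genes. A list score is, per tumour, the median over its genes of the signal relative to the control mean. Figures were drawn with matplotlib 3.10.9.

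The lists, the rule for named genes, the tests of genes and lists between groups and the alternatives were fixed before the data were examined; the closing tests on muscle and intestinal genes were not. The lists hold 918 genes, of which 829 were tested. Named genes are the 6 largest rises and 6 largest falls among genes past the threshold, passing over names that are not symbols, then 10 genes always reported, and for each list described up to 4 members with the smallest p. Genes named outside this rule are said to be so. The alternatives were quantile scaling, normexp background correction with an offset of 50 and quantile scaling, the authors' value table, no filter on dim probes, a filter on all 6 arrays, the mean of a gene's probes, a block for the replicate number, variance trend with robust estimation, array weights, leaving out each tumour, a per-gene test without variance moderation, and camera with a preset correlation of 0.01 or an estimated one.

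The analysis was tested on simulated data with the spread per gene of these arrays. In the test of genes, genes varied independently and 22746 of 22946 were unchanged. In the arrays genes vary together and 27.3% differed at an unadjusted p under 0.05 (limma). The shares below therefore need not hold for the arrays. For the comparison of miR-124a with control over 22946 genes, it called 19.4% of genes changed 1.5-fold, 55.2% of those changed 2-fold, 84.8% of those changed 4-fold and 0.0264% of unchanged genes. With fry, 8.75% of lists shifted by 0.5 on the log2 scale and 80.0% of those shifted by 1 were called, in tumours that also varied by a shared factor with an SD of 0.2. Of the unshifted lists, 0.192% and 0.769% were called in these runs. In the arrays, control scores of the lists had SDs from 0.04 (p53 response) to 0.70 (erythroid cells). All 6 arrays lay on 1 slide and were scanned together, with control tumours in slide row 1 and miR-124a tumours in row 2, so slide row and group cannot be told apart and no block for slide or scan could be fitted. A test of seed sites in 3' untranslated regions needed transcript sequences and was not analysed here.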

Results

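Messenger RNA was profiled in 6 teratomas grown from mouse embryonic stem cells, 3 given a microRNA negative control and 3 given a miR-124a-3p mimic. The microRNA was injected into the tumour at 15 µg per 100 µL every 3 days to day 28, starting about 10 days after the cells were implanted, when tumours had reached 100 mm3. miR-124 is a microRNA abundant in neurons. Across genes, which are not independent replicates, arrays correlated at 0.9857 to 0.9886 among control tumours, at 0.9882 to 0.992 among miR-124a tumours and at 0.9705 to 0.9868 between groups. The 75th percentile of spot intensity lay between 278.6 and 315.2. Control tumours lay in 1 row of the slide and miR-124a tumours in the other, so every difference below is also a difference between slide rows.

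The comparison asked whether the mimic altered gene expression in the tumours. As lists, the genes of skeletal muscle, cardiac muscle and the intestinal lining were lower in the miR-124a tumours (fry), with 27 of 32, 6 of 19 and 6 of 18 of their tested genes past the threshold over all genes. Camera asks another question than fry, since it compares a list with the other genes. With an estimated correlation between genes it called 0 of 35 lists (adjusted p = 0.51 for each of these 3). With a preset correlation camera called all 3 (adjusted p = 8.91e-23, 2.12e-06 and 2.1e-05). The neuron list had higher values and did not pass with fry, except with normexp background correction. The largest fall was that of Gkn2, a secreted protein of the stomach surface (probe on chromosome 6, 87329285 to 87329344, build mm9), which was 27.4-fold lower with a log2 fold change of -4.78 ± 0.33 (SE, n = 3 per group) and an adjusted p of 0.0135. Fabp1, the fatty acid binding protein of liver and intestine (chromosome 6, 71154906 to 71154965), fell by 2.88 ± 0.19 on the log2 scale and was well above background on 1 of 3 miR-124a arrays. Gsdma2, a gasdermin gene, fell by 3.13 ± 0.37, and Mucl3, a mucin-like gene well above background on 2 of 3 miR-124a arrays, by a log2 fold change of -3.23 ± 0.55. Normexp background correction with quantile scaling, named normexp from here, draws dim values together and gave -3.26 for Gkn2, -0.87 for Fabp1, -1.45 for Gsdma2, -1.09 for Mucl3, -0.84 for Reg1 and -0.34 for Cyp2c65, each past the threshold. Reg1, a secreted lectin of pancreas and gut, was at least 7.37-fold lower (adjusted p = 0.0211), and Cyp2c65, a cytochrome P450, at least 2.19-fold lower (adjusted p = 0.0135), since neither was well above background in any miR-124a tumour.

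The largest rises were in dim genes. Vmn1r197, of the large vomeronasal receptor family whose members are similar in sequence, was at least 2.32-fold higher (adjusted p = 0.0242) and not well above background in any control tumour. Adamtsl3, Ifna1 and Efcab3 rose by 2.24 ± 0.36, 1.17 ± 0.20 and 1.16 ± 0.21 on the log2 scale, each well above background on 1 of 3 control arrays. L3mbtl1, a chromatin-binding protein, rose by 1.41 ± 0.22 at its brighter probe and had 0.08 at the other (0.74 for their mean, adjusted p = 0.0559), and Tmprss9, a membrane serine protease, rose by 1.12 ± 0.19. With normexp Ifna1, Efcab3 and Tmprss9 did not pass (log2 fold changes of 0.16, 0.20 and 0.28, adjusted p = 0.142, 0.0781 and 0.0735), nor did Tmprss9 with array weights (0.0596), and Vmn1r197, Adamtsl3 and L3mbtl1 passed at 0.26, 0.40 and 0.39. Ifna1 belongs to the closely similar type I interferon genes.

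Of 22946 genes tested, 742 changed (limma, adjusted p under 0.05), 112 higher and 630 lower with miR-124a, so that 84.9% of the calls were lower. With normexp background correction and quantile scaling 1549 genes changed, 581 higher and 968 lower (62.5% lower), and without a filter on dim probes 96 of 37001 changed. At an unadjusted p under 0.05, 6268 genes (27.3%) differed, and 751 of these had a fold of at least 2, 167 higher and 584 lower. The values of the groups did not overlap for 8165 genes (35.6%), against a mean of 10% over all splits of the 6 arrays into 3 and 3. Genes vary together, so a single split can lie well above that mean by chance. Leaving out any 1 tumour lowered the count. It was 13 without control 1 (6117 at an unadjusted p under 0.05, limma), 0 without control 2 (4785) and 353 without control 3 (6074). It was 1 without miR-124a 1 (4936 unadjusted), 0 without miR-124a 2 (4103) and 375 without miR-124a 3 (4916). All 742 genes kept their direction in each of these 6 fits, but they were picked for large differences in the same arrays, so this was largely set in advance. Each fit has 1 tumour fewer, so the counts do not separate a loss of power from dependence on 1 tumour. Of the 55 genes that passed and were named by the fixed rule, 11 passed without the filter on dim probes. Leaving out a tumour, 4 of them passed without control 1, 0 without control 2, 26 without control 3, 1 without miR-124a 1, 0 without miR-124a 2 and 29 without miR-124a 3.

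**Figure D1:**
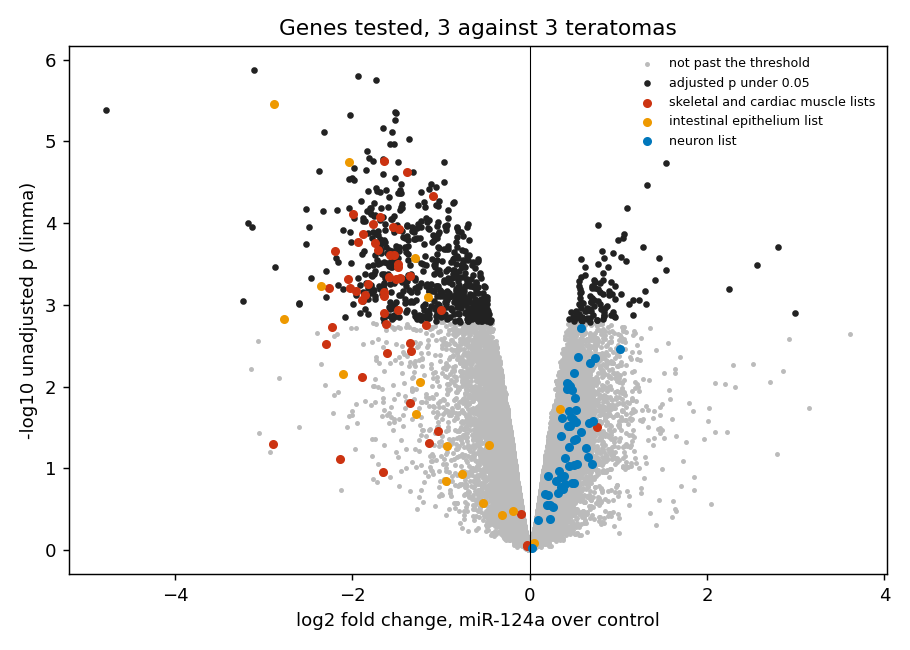
Each point is 1 of 22946 genes, with the log2 fold change of miR-124a over control on the x axis and -log10 of the unadjusted limma p on the y axis; black points passed the threshold on the adjusted p (112 higher, 630 lower), and coloured points belong to the muscle, intestinal and neuron lists. Muscle genes lie mostly on the left, and the neuron genes lie on the right without passing.

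All 32 tested genes of the skeletal muscle list had lower values with miR-124a, 27 of them past the threshold over all genes and 32 adjusted over the list alone, with a median log2 fold change of -1.67 (fry, adjusted p = 0.0223; adjusted p = 0.51 with an estimated correlation). The regulators of muscle formation Myod1 and Myog fell by 1.99 ± 0.22 and 1.65 ± 0.14 on the log2 scale (adjusted p = 0.0211 and 0.0170). Chrna1, an acetylcholine receptor subunit, and Ryr1, the calcium release channel, fell by 1.77 ± 0.21 and 1.69 ± 0.19; the 3 probes of Ryr1 ran from -2.31 to -0.66. The count of 27 fell to 1 without control 1, to 14 without control 3 and to 0 without control 2, miR-124a 1 or miR-124a 2, and it was 1 of 33 without the filter on dim probes. The list call was lost without control 1 (adjusted p = 0.104), control 2 (0.0673), miR-124a 1 (0.098) or miR-124a 2 (0.0889).

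Of 19 tested cardiac muscle genes 6 fell and 13 did not pass, with 10 lower when adjusted over the list alone, and the list's median was -1.39 (fry, adjusted p = 0.0123; adjusted p = 0.51 with an estimated correlation). Actc1, cardiac actin, fell by 1.39 ± 0.13, and the troponins Tnnc1 and Tnnt2 and the light chain Myl3 fell by 1.09 ± 0.11, 1.47 ± 0.17 and 1.71 ± 0.23; these are also made by developing or slow skeletal muscle. Without control 1 the list had an adjusted p of 0.104, and without miR-124a 1 of 0.074. Its count of 6 genes was 0 without control 1, control 2, miR-124a 1 or miR-124a 2, 3 without control 3, and 2 of 24 without the filter. In the smooth muscle and pericyte list 5 of 18 genes fell and 13 did not pass, with 7 lower over the list alone and a median of -0.28, or -0.17 with normexp (fry, adjusted p = 0.0223; adjusted p = 0.585 with an estimated correlation). Acta2, smooth muscle actin, fell by 1.14 ± 0.11, Smtn by 1.27 ± 0.16 and Actg2 by 0.95 ± 0.11; probes of Synpo2 disagreed, from -1.73 to 0.49, with -0.99 for their mean. The call of this list was lost without control 1 (adjusted p = 0.12), miR-124a 1 (0.109), miR-124a 2 (0.133) or miR-124a 3 (0.0536), and with the mean of a gene's probes (0.0738). Its count of 5 was 0 without control 1, control 2, miR-124a 1 or miR-124a 2, and 1 of 19 without the filter on dim probes.

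**Figure D2:**
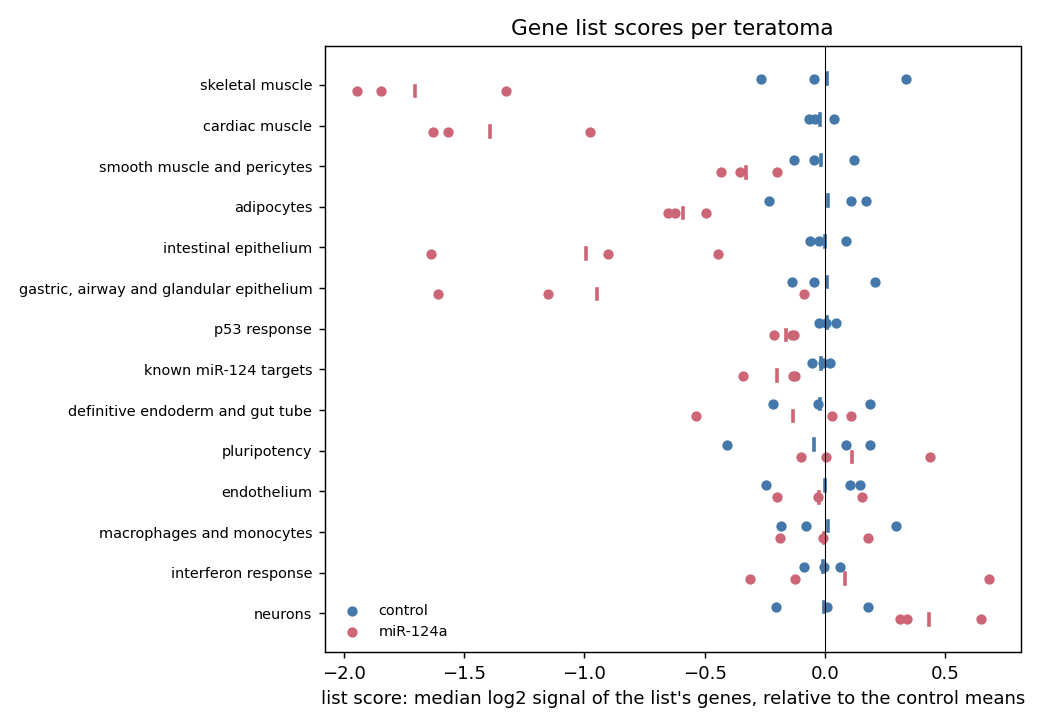
Scores of 14 gene lists in each tumour: points are tumours, bars are group means, and the x axis is the median log2 signal of a list's genes relative to the control means. The 3 miR-124a tumours have skeletal muscle scores from -1.95 to -1.33 and the 3 control tumours from -0.27 to 0.34.

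The intestinal list was lower as well. Of 18 tested genes 6 fell and 12 did not pass, with 9 lower and 1 higher adjusted over the list alone, at a median of -1.05 (fry, adjusted p = 0.0223; adjusted p = 0.51 with an estimated correlation). The median was -0.40 with normexp and quantile scaling (adjusted p = 0.0212) and -0.67 without miR-124a 2. Fabp2, the intestinal fatty acid binding protein, fell by 2.04 ± 0.18 (-0.66 with normexp), Lgals4, a galectin of the gut, by 1.29 ± 0.18, and Zg16, a protein of the mucus layer, was at least 3.18-fold lower (adjusted p = 0.0350), while normexp gave it a log2 fold change of -0.38 that did not pass (adjusted p = 0.0586). The score was at most -0.44 in the 3 miR-124a tumours (mean -0.99 ± 0.60 SD) and 0.00 ± 0.08 in controls, an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allow. The tumour miR-124a 2 had the lowest score, -1.64, beside -0.90 in miR-124a 1 and -0.44 in miR-124a 3, and other lists had the same order of these tumours. In that order the scores were -1.61, -1.15 and -0.09 for the gastric, airway and glandular list, -0.91, -0.43 and 0.33 for keratinocytes, -0.77, -0.11 and 0.09 for simple epithelium, and -0.90, -0.56 and 0.26 for neutrophils. The list call was lost without control 1 (adjusted p = 0.124), control 2 (0.0926), control 3 (0.0591), miR-124a 1 (0.0899) or miR-124a 2 (0.0696), and when genes had to be above background on all 6 arrays (0.0769). The count of 6 genes was 0 without control 1, control 2 or miR-124a 2, 1 without miR-124a 1, 3 without control 3, 3 of 14 with that filter and 2 of 26 with none. The gastric, airway and glandular list did not pass (median -0.94, fry, adjusted p = 0.0765, from 0.000773 to 0.585 over the alternatives), and miR-124a 3 lay within its control scores of -0.14 to 0.21. Its median was -0.53 without miR-124a 2 and -1.38 without miR-124a 3, where it passed (adjusted p = 0.0375), as it did by camera with a preset correlation (0.000773). In this list 4 of 20 genes fell, among them Gkn2 and Tff1, a trefoil peptide of the stomach that fell by 2.87 ± 0.41, while Aqp5 and Gkn3 fell by 0.94 ± 0.16 and 1.58 ± 0.28 (Gkn3 -1.02 with normexp). The count of 4 was 1 without control 1 or control 3, 0 without control 2, miR-124a 1 or miR-124a 2, and 1 of 21 without the filter on dim probes.

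The p53 response list was lower by a small amount, with a median of -0.12 over 22 genes (-0.08 with normexp), of which 4 fell and 18 did not pass (5 lower over the list alone; fry, adjusted p = 0.0123; adjusted p = 0.51 with an estimated correlation). Those that fell were Eda2r, a receptor of the tumour necrosis factor family (-1.52 ± 0.18), Ak1, an adenylate kinase abundant in skeletal muscle (-1.01 ± 0.17), Ccng1, a cyclin (-0.65 ± 0.11), and Pmaip1, a promoter of cell death (-0.71 ± 0.13); the skeletal muscle list was lower in the same tumours by a median of -1.67. Without control 1, miR-124a 1 or miR-124a 2 the adjusted p of the p53 response list was 0.104, 0.074 and 0.0696 (fry). Camera with the preset correlation of 0.01 called this list (adjusted p = 0.0181). Its estimated correlation was -0.0132, below the preset, so the loss of the call with the estimate cannot be put down to correlation within this list. Its count of 4 was 2 without control 3, 1 without miR-124a 3, and 0 in the other 4 fits that leave out a tumour and without the filter on dim probes. The adipocyte list was lower with a median of -0.64 over 20 genes, or -0.38 with normexp, and 1 of them, the fatty acid transporter Cd36, fell (-0.81 ± 0.13, or -0.46 with normexp), with 8 lower over the list alone (fry, adjusted p = 0.0361; adjusted p = 0.51 with an estimated correlation). Ucp1, Lpl and Car3 had log2 fold changes of -2.02, -0.70 and -1.78 and did not pass (adjusted p = 0.0532, 0.0544 and 0.0609). Ucp1 was well above background on 1 of 3 miR-124a arrays, and the 6 probes of Lpl ran from -0.76 to 0.20. With normexp 4 genes of the list fell, and Ucp1, Lpl and Car3 had -0.43, -0.64 and -1.62 (adjusted p = 0.054, 0.0224 and 0.0439). Without control 1, control 2, miR-124a 1, miR-124a 2 or miR-124a 3 the list's adjusted p was 0.12, 0.128, 0.207, 0.125 and 0.0908, and with the filter on all 6 arrays it was 0.0503. Of the 6 fits that leave out a tumour, Cd36 passed in that without miR-124a 3 alone, and it did not pass without the filter on dim probes.

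Genes named in earlier work as miR-124 targets were lower by little and did not pass as a list. Of 49 tested, 3 fell and 46 did not pass, with 10 lower and 1 higher over the list alone, and the median was -0.21, or -0.14 with normexp (fry, adjusted p = 0.0765 and 0.166). Plp2 and Cd164, both membrane proteins, fell by 1.04 ± 0.15 and 0.69 ± 0.11, and Tead1, a transcription factor of the Hippo pathway, by 0.51 ± 0.09 (adjusted p = 0.0428, or 0.0506 with quantile scaling). The count of 3 was 0 in each of the 6 fits that leave out a tumour and 0 without the filter on dim probes. Itgb1, an integrin, had a log2 fold change of -0.54 (adjusted p = 0.0521), or -0.46 with normexp (adjusted p = 0.0263). With normexp 9 genes of the list fell and 1, Sox9, rose (0.43, adjusted p = 0.017). In the scaling used here Sox9 had 0.40 ± 0.08 (adjusted p = 0.059), against the direction of repression. Ptbp1, a splicing repressor that neurons switch off, had a value of -0.17 ± 0.14 (adjusted p = 0.468), with probes from -0.17 to 0.32 and values of 0.08 for the mean of its probes, -0.10 with normexp, -0.28 without miR-124a 1 and -0.04 without miR-124a 2. Ctdsp1, a phosphatase of neural gene repression, stood at -0.64 ± 0.24 (adjusted p = 0.160).

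Genes of early endoderm did not pass as a list: the 18 tested had a median of -0.13 (fry, adjusted p = 0.405), and 3 fell while 15 did not pass. Those that fell were Ihh, a hedgehog ligand (-1.20 ± 0.18), Isl1 (-1.06 ± 0.17) and Hnf4a (-1.40 ± 0.25). Ihh and Hnf4a had -0.66 and -0.45 with normexp, and Hnf4a did not pass with array weights (adjusted p = 0.0626). Each of these 3 genes lost its call in 8 of 15 alternatives. Gata4, a transcription factor of the same list, had -1.67 ± 0.47 and did not pass (adjusted p = 0.0949). It was not well above background on any miR-124a array, which makes the fold at least 2.37, and its values ran from -1.95 to -0.22 over the alternatives. Sox17 and Gata6, transcription factors of endoderm, had log2 fold changes of 0.15 ± 0.15 (adjusted p = 0.562) and -0.61 ± 0.37 (adjusted p = 0.324), and Afp, of yolk sac and fetal liver, had -1.67 ± 0.92 (adjusted p = 0.285). These values rested on single tumours. Afp had -0.70 without control 3 and -1.07 without miR-124a 2, and Gata6 had -0.93 without miR-124a 1, -0.23 without miR-124a 3 and -0.25 with normexp. Sox17 had 0.27 without control 1, 0.06 without control 2 and 0.05 without miR-124a 2. The median of the early endoderm list turned to 0.03 without control 3 and to 0.02 without miR-124a 2. The yolk sac and hepatic endoderm list, which holds Afp, did not pass (median -0.27 over 18 genes, fry, adjusted p = 0.083). Of its genes Apoa4 fell by 2.04 ± 0.19, or 0.50 with normexp (limma, adjusted p = 0.0194 and 0.023). Alb had -2.83 (adjusted p = 0.0836), Apoa1 -1.615 (0.125) and Apoa2 -0.56 (0.0609). Alb was well above background on 1 of 3 miR-124a arrays and Apoa1 on 0. The pluripotency list had a median of 0.10 over 31 genes (fry, adjusted p = 0.938), with Pou5f1 at -0.24 ± 0.23 and Nanog at -0.20 ± 0.10 (adjusted p = 0.525 and 0.252), or -0.14 and -0.12 with normexp; 1 gene, Tbx3, fell (-1.14 ± 0.19). The list's median was -0.25 without control 2 and -0.06 without miR-124a 1. Pou5f1 had -0.39 without control 2, -0.14 without control 3, and -0.46, -0.12 and -0.13 without miR-124a 1, 2 and 3, and Nanog had -0.13 without miR-124a 3.

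**Figure D3:**
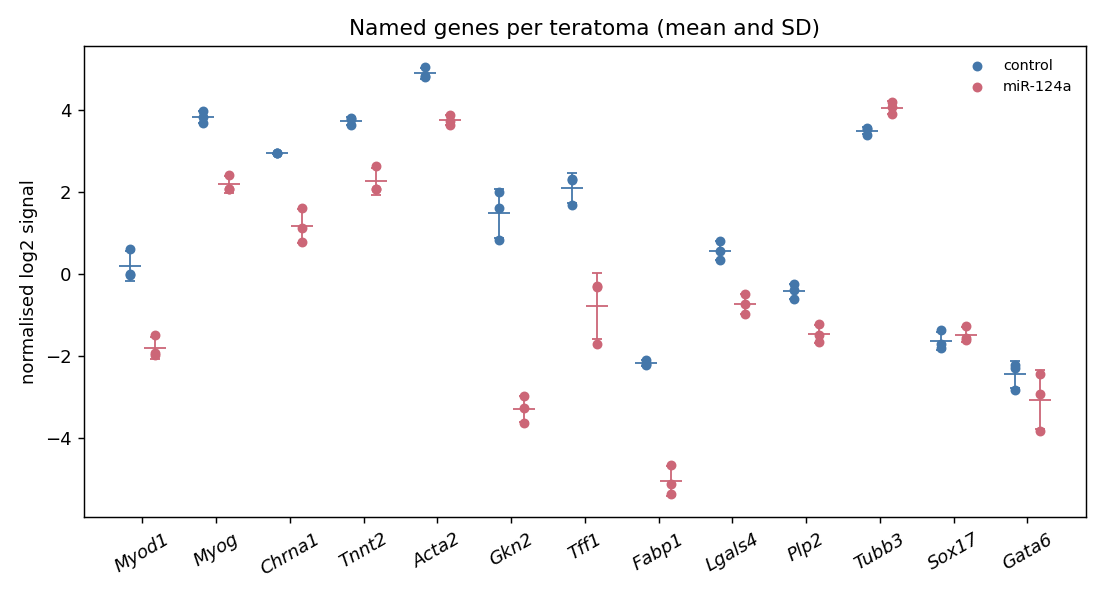
Normalised log2 signal of 13 named genes in each tumour, with the mean and SD of the 3 tumours of a group. The muscle and gut genes lie lower in all 3 miR-124a tumours, and the values of Sox17 and Gata6 overlap between groups.

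Neuron genes had higher values in the miR-124a tumours. In the scaling used here the list did not pass with fry, and no member passed in the main limma fit. All 53 tested genes were higher in value, with a median of 0.44, 0 called over all genes or over the list alone (limma; smallest unadjusted p 0.00191) and a fry adjusted p of 0.083. With normexp the list had an adjusted p of 0.0497 and 17 of the 53 genes rose. In the scaling used here, camera gave the list an adjusted p of 1.9e-11 with a preset correlation and 0.585 with an estimated one. Of the list's genes 8 rose with variance trend and robust estimation and 3 with quantile scaling. Tubb3, a tubulin of neurons, had a log2 fold change of 0.57 ± 0.11 (adjusted p = 0.0531), Eomes 1.02 ± 0.23 (0.0656), Myt1l 0.74 ± 0.17 (0.0714) and Elavl2 0.54 ± 0.13 (0.0708). With normexp these 4 genes had 0.71, 0.32, 0.79 and 0.64 (adjusted p = 0.0157, 0.0459, 0.0328 and 0.026). Pax6, of neural progenitors, had 0.46 ± 0.14 (adjusted p = 0.114). The neural progenitor list did not pass (median 0.20 over 31 genes, fry, adjusted p = 0.863), with 21 genes higher and 10 lower in value. Its 4 genes with the smallest p were lower in value. Pax7, also of the skeletal muscle list, fell by 1.94 (limma, adjusted p = 0.0232), and Emx2, Hes6 and Nes had -0.71, -0.62 and -0.61 without passing. Sox9, of the astrocyte, cartilage and miR-124 target lists, had 0.40 ± 0.08 (adjusted p = 0.059), with probes from -0.04 to 0.40. Sox9 had 0.43 with normexp (adjusted p = 0.017) and 0.18 for the mean of its probes. The score of the neuron list was 0.31 to 0.65 in miR-124a tumours and -0.20 to 0.18 in controls, an exact two-sided permutation p of 0.1.

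In all, 6 of 35 lists passed, all lower. Without control 1 or miR-124a 1 none passed (fry; 12 and 8 lists at an unadjusted p under 0.05), and without miR-124a 2 cardiac muscle alone did. Without control 2, 3 of the 6 passed (cardiac muscle, smooth muscle and p53 response), along with yolk sac and hepatic endoderm (median -0.41, adjusted p = 0.00562). Without control 3, 5 of the 6 passed, along with astrocytes and radial glia (0.14, adjusted p = 0.0457). Without miR-124a 3, 4 of the 6 passed, along with the gastric list and neutrophils (-0.64, adjusted p = 0.0498). The lists of endothelium, macrophages and interferon-responsive genes did not pass (fry, adjusted p = 0.916 each), and in 4 lists (endothelium, cartilage, choroid plexus with retinal pigment epithelium, and pancreas) the signs of median, mean and test differed. With fry's test for change in either direction 21 lists passed. Among them were definitive endoderm (adjusted p = 0.00187), neural progenitors (0.00187), known miR-124 targets (0.00283) and neurons (0.0202), while pluripotency did not pass (0.249). That test does not ask whether the genes of a list move the same way. The fibroblast and matrix list had a median of -0.29 (adjusted p = 0.0765), and its genes Prrx1, Fbn1 and Ogn fell by 0.86 ± 0.09, 0.56 ± 0.10 and 0.93 ± 0.16, with probes of Fbn1 from -0.63 to -0.13 and no call for their mean (-0.44, adjusted p = 0.0777). The cell cycle list had -0.26 (adjusted p = 0.580) with none of its 43 genes called (limma; smallest unadjusted p 0.0172), and its median was -0.10 without control 3, -0.16 without miR-124a 2 and -0.40 without miR-124a 1. Camera with a preset correlation called both lists, and with an estimated one neither.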

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

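Every alternative below was planned. The count of genes changed was 1549 with normexp and quantile scaling, 96 of 37001 without a filter on dim probes, 1723 with variance trend and robust estimation, and 0 with a per-gene test without variance moderation (5502 at an unadjusted p under 0.05); quantile scaling, the value table, the filter on all 6 arrays, probe means and array weights gave 847, 718, 764, 731 and 732. All main calls that were tested kept their direction under every alternative. With the block, variance trend or the test without moderation the log2 fold changes are those of the main fit, so no direction could change. The calls were also picked for large differences in these same arrays, so kept directions are weak evidence that the calls hold. Genes with a fold of at least 2 and an unadjusted p under 0.05 numbered 254 with normexp and 1130 without the filter. Leaving out each tumour gave 0 to 375 genes and 0 to 6 lists. Camera called 13 lists with a preset correlation, among them known miR-124 targets (-0.21) and neurons (0.44), and 0 with an estimated correlation, where the medians are those reported: skeletal muscle -1.67, cardiac muscle -1.39, intestinal epithelium -1.05, adipocytes -0.64, smooth muscle -0.28 and p53 response -0.12. Calls were also lost for intestinal epithelium (-0.85) and adipocytes (-0.58) with the filter on all 6 arrays, and for smooth muscle with probe means (-0.19), while neurons passed with normexp (0.52). The cause was not tested. Over the fits without 1 tumour the medians ranged from -1.90 to -1.57 for skeletal muscle, -1.59 to -1.28 for cardiac muscle, -1.35 to -0.67 for intestinal epithelium, -0.69 to -0.50 for adipocytes, -0.35 to -0.22 for smooth muscle, -0.16 to -0.11 for p53 response, -0.25 to 0.31 for pluripotency and -0.233 to 0.034 for definitive endoderm.

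With the replicate number as a block 0 genes (4952 unadjusted) and 0 lists were called, at the same medians (-1.67, -1.39, -1.05, -0.64, -0.28, -0.12). The numbers did not pair the tumours: correlations of deviations for same-numbered tumours were -0.16, -0.04 and -0.06, and no tumour correlated best with its own number.

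Among lists that did not pass, medians changed sign for endothelium (0.020 with quantile scaling, 0.003 with normexp, 0.021 with probe means), immediate early and heat shock genes (0.029 with quantile scaling, 0.008 with normexp), pancreas (0.004 with normexp, 0.040 without the filter, 0.350 with the filter on all arrays), erythroid cells (-0.037 with that filter), and with array weights choroid plexus (-0.036) and macrophages (-0.044). Ptbp1 turned to 0.077 with probe means. Without 1 tumour the ranges were -0.097 to 0.411 for lymphocytes and mast cells, -0.428 to 0.386 for erythroid cells, -0.192 to 0.265 for interferon response, -0.003 to 0.431 for motile cilia, -0.131 to 0.017 for pancreas, -0.040 to 0.154 for choroid plexus, -0.013 to 0.151 for cartilage, -0.130 to 0.072 for endothelium and -0.083 to 0.155 for macrophages. The seed-site test and the slide block were not run, for lack of transcripts and of a second slide. Of 56605 probes, 63.4% to 65.9% were well above background on an array, which limits what dim genes can show.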

Other observations

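Genes in this paragraph were chosen after their values were seen. All 5 subunits of the muscle acetylcholine receptor fell, Chrna1, Chrnb1, Chrnd, Chrne and Chrng, with log2 fold changes from -1.77 to -1.34. Mstn, which restrains muscle growth, fell by 1.81 ± 0.15, while the growth factors Igf2 and Igf1 fell by 1.32 ± 0.22 and 1.06 ± 0.10 (limma, adjusted p = 0.04 and 0.0194). Pga5, a pepsinogen of the stomach, fell by 2.47 ± 0.37 and Ghrl, the precursor of ghrelin, by 2.16 ± 0.30. Mir124a-1hg, a host transcript of the animal's own miR-124, rose by 0.84 ± 0.15 (adjusted p = 0.0465). Its probe does not measure the mimic. Celsr3, Nexmif, Sv2c, Plxna3, Rims2, Astn1 and Brsk2, neuronal genes outside the fixed neuron list, also rose, by 0.57 to 0.87 (limma, adjusted p from 0.0279 to 0.0474). Neuronal genes outside that list that fell or did not change were not counted.

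The tests on muscle and intestinal genes below were chosen only after those results were seen; the tests on splits and on miR-124 targets were written before their results. The 6 arrays can be split into 3 and 3 in 10 ways, so the share of splits with as large a result cannot go under 0.1 and these splits are too few to tell: the real split, 1 of 10, gave 742 genes changed, 751 genes with a fold of at least 2 and an unadjusted p under 0.05, and 6 lists, and the highest of the others gave 0 (limma; up to 1241 at an unadjusted p under 0.05), 152 and 1.

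The fall of muscle genes could come from adult muscle of the host in the control pieces. The 10 tested genes of developing muscle among the fixed lists, which adult fibres hold little of, had a median log2 fold change of -1.52 (-1.37 with normexp). All of them fell, beside a median of -2.03 for 11 genes of adult fibres. The fall was thus not confined to genes of adult fibres. The division was made after the values of the lists were seen, so its outcome was largely known and host muscle is not excluded. A difference in labelling or hybridisation between slide rows that acts on spots by brightness is argued against by the spike-in controls: across 8 well above background, the largest difference between rows was 0.128. All 8 were lower in the miR-124a row, from -0.128 to -0.059, while the median over all genes was -0.002. The p53 response median (-0.12) is of that size, so the spike-ins do not argue against a row difference for shifts that small. Differences between tumours or their handling that follow the slide row cannot be told apart from the treatment. A lower share of muscle in the treated tumours is a hypothesis that these tests leave open.

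A smaller share of muscle alone would raise the markers of every other cell type alike. The intestinal score minus the endothelium score was lower by -0.97 with miR-124a, with the tumours of the groups apart (at most -0.42 against at least -0.13), and by -0.38 with normexp, again apart (at most -0.16 against at least -0.09). Fewer epithelial cells of every kind would lower intestinal and simple epithelium genes alike; that difference was -0.75 (at most -0.53 against at least -0.16), and -0.25 with normexp. Both differences passed the 0.5 set for these tests in the scaling used here and missed it with normexp, so by that rule neither explanation is excluded. A smaller muscle share alone predicts a higher intestinal score, yet the score itself was lower. It was at most -0.44 with miR-124a against at least -0.06 in controls, and at most -0.16 against at least -0.03 with normexp. For this list in these tumours, that argues against a smaller muscle share as the whole cause. A lower share of intestinal tissue, by treatment or by chance differences in what each tumour piece held, was not tested and stays open too.

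The known miR-124 targets had a median of -0.21, and 0 of 10000 random lists matched on mean signal had a median as low (95% of them from -0.11 to 0.07), or 2 of 10000 with normexp, so a downward skew of genes of like brightness is argued against; this describes these arrays, since genes in a list vary together. Their lower values may follow the muscle content of the tumours. With the skeletal muscle score as a covariate the difference in target score went from -0.18 to -0.03, with a 95% interval from -0.90 to 0.85, too wide to tell repression by the mimic from a change in tissue makeup.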
